A study of Triticum aestivum and Aegilops tauschii and Triticum carthlicum with 33 samples.

How the data were processed

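Leaf RNA was profiled on the Affymetrix wheat GeneChip in 33 arrays, 3 labelled biological replicates in each of 11 groups. Per the labels, plants grew in chambers at 24 °C by day and 20 °C by night with 16 h of light, and biotin-labelled cRNA was made from 6 µg of total RNA. The deposited values are log2 expression summaries, 1 per probe set and array; the submitters' processing notes name RMA and limma without versions. The matrix held 61290 probe sets, of which 111 were Affymetrix controls, and the other 61179 were tested. The values lay on a log2 scale and no array duplicated another. Arrays carry no read depth, and their number limits the precision.

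Groups were taken from the labels. The natural tetraploids were TTR13, TD265 and Blackbird, the Aegilops tauschii lines were TQ18 and 30A, and the labels gave no batch. A cell-means model of the 33 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 22 residual and 28.51 total degrees of freedom after moderation). P values were adjusted by the Benjamini-Hochberg method within each of 14 contrasts, and a probe set was called at an adjusted p under 0.05. All log2 differences are first minus second group. The error of each test came from arrays within a group. Where several lines are averaged, the p values therefore do not measure the spread between lines. A further count took probe sets called in 1 direction against each of the natural tetraploids. The hexaploids were compared with physical RNA mixes of their parents, and an interaction contrast compared the departures of the hexaploids from these mixes. In 4 tests of directed sets, probe sets called in 1 contrast were signed by its direction and tested in a contrast of other arrays with fry, limma's rotation test (2-sided, Benjamini-Hochberg over the 4). Beside these stand exact permutation tests (2-sided) of the mean score per array. With 3 arrays against 3, an exact p cannot fall under 0.1. Comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined; the covariate, the added gene groups, the exchange of whole lines and the sets of arrays given below were chosen afterwards.

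Probe sets were named through the platform annotation, which assigned 1273 probe sets to 771 genes, 1 symbol each; 59906 tested probe sets had no symbol. By Entrez gene ID, 1272 of the 1273 matched a RefSeq annotation (assembly IWGSC CS RefSeq v2.1, used for names only). Of these genes, 102 had a name or alias other than LOC and digits, and each was read from the probe set with the highest mean over all arrays, avoiding those of the x type, with probes shared between unlike transcripts, where another existed. Probe sets of the s type, shared by several transcripts, were not avoided, and rbcl was read from such a one. The genes named are, for each main comparison, the 10 highest and 10 lowest log2 differences among called genes whose arrays did not overlap between the groups, plus the 2 called members of each gene list with the smallest adjusted p; for the other comparisons, the 3 highest and the 3 lowest. Of 20 gene lists, 16 held 1 to 4 named genes and 4 held none, so the planned camera test, which needed 5 genes, was not run. The flowering time list matched only the cold-regulated gene COR410, by the letters of an alias. In place of the planned test, 6 groups of the named genes were tested with camera (preset correlation 0.01) in the 14 contrasts, 84 tests in all.

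As a check of the labels, D-enriched probe sets were called and at least 4-fold higher in both Aegilops tauschii lines than in each natural tetraploid, and BBAA-enriched probe sets at least 4-fold lower. Each mix was also compared with a mix calculated from its parents' arrays. Control probe sets were read on each array, with the difference of the 3′ and 5′ actin probe sets taken as a measure of RNA quality.

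Replicate numbers were taken to pair arrays of a pair of groups only where every same-numbered pair correlated above 0.1 after group means were removed. TQ18 and 30A alone met this (r across probe sets 0.1 to 0.14, best with the own number in 3 of 3), and with the replicate as a block the count for that pair was 11189 in place of 11298. Other pairs of groups were treated as unpaired.

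Alternatives were a 2-fold minimum, the dimmest 33.3% of probe sets left out, median centring, centring on the hybridisation controls, quantile normalization again, eBayes with trend and robust settings, array weights, probe sets with shared probes left out, the replicate as a block, a fit limited to the groups compared, each array left out, calculated mixes, each line left out of a mean, a fit without the 12 arrays of the Allo-960 family, and the actin difference as a covariate. Tested on simulated data of the same size with 200 changed probe sets, the fit recovered 58% of 1.5-fold and 98% of 2-fold changes for Extracted-tetra against TAA10. It recovered 38% and 94% for XX329 against its mix, and 26% and 94% for Allo-960S7 against its mix. In these runs 4 to 7 unchanged probe sets were called, and the smallest change simulated was recovered in 0% to 6%. The noise was drawn independently for each probe set and array, so errors shared across an array were not simulated. The number of false calls therefore does not carry over to the data. In the data these comparisons called 1152 to 11206 probe sets, more than were changed in the simulation. The adjusted cut-off was therefore stricter in the simulation, and these shares may understate the recovery in the data. Tables and plots used the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe-level intensities were not used here, so probe mismatches between species and homoeologs could not be examined.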

Results

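Leaf transcripts were measured in 33 arrays of 11 groups, 3 arrays each. TTR13 (durum wheat), TD265 (wild emmer, subspecies dicoccoides) and Blackbird (subspecies carthlicum) were natural tetraploids with the BBAA genomes. TQ18 and 30A were lines of the diploid Aegilops tauschii, which carries the D genome. TAA10 was a bread wheat with all 3 genomes, and Extracted-tetra was a tetraploid carrying the BBAA genomes taken out of TAA10. XX329 was a hexaploid resynthesized from Extracted-tetra and TQ18. Allo-960S7 was a synthetic hexaploid, in selfed generation 7, from Blackbird and 30A. For each hexaploid the parents' RNA had been mixed physically, 2 parts tetraploid to 1 part diploid, as a stand-in for additive expression. Arrays of 1 group correlated across probe sets with r from 0.9792 to 0.996, and the median r between groups was 0.9433. The array medians lay between 4.37 and 4.481 log2 units, and below them a fold is not secure because background was not measured. Component 1 of the principal component analysis (54.4% of the variance) set the Aegilops tauschii arrays apart from the tetraploids, with all hexaploids and mixes in between.

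**Figure D1:**
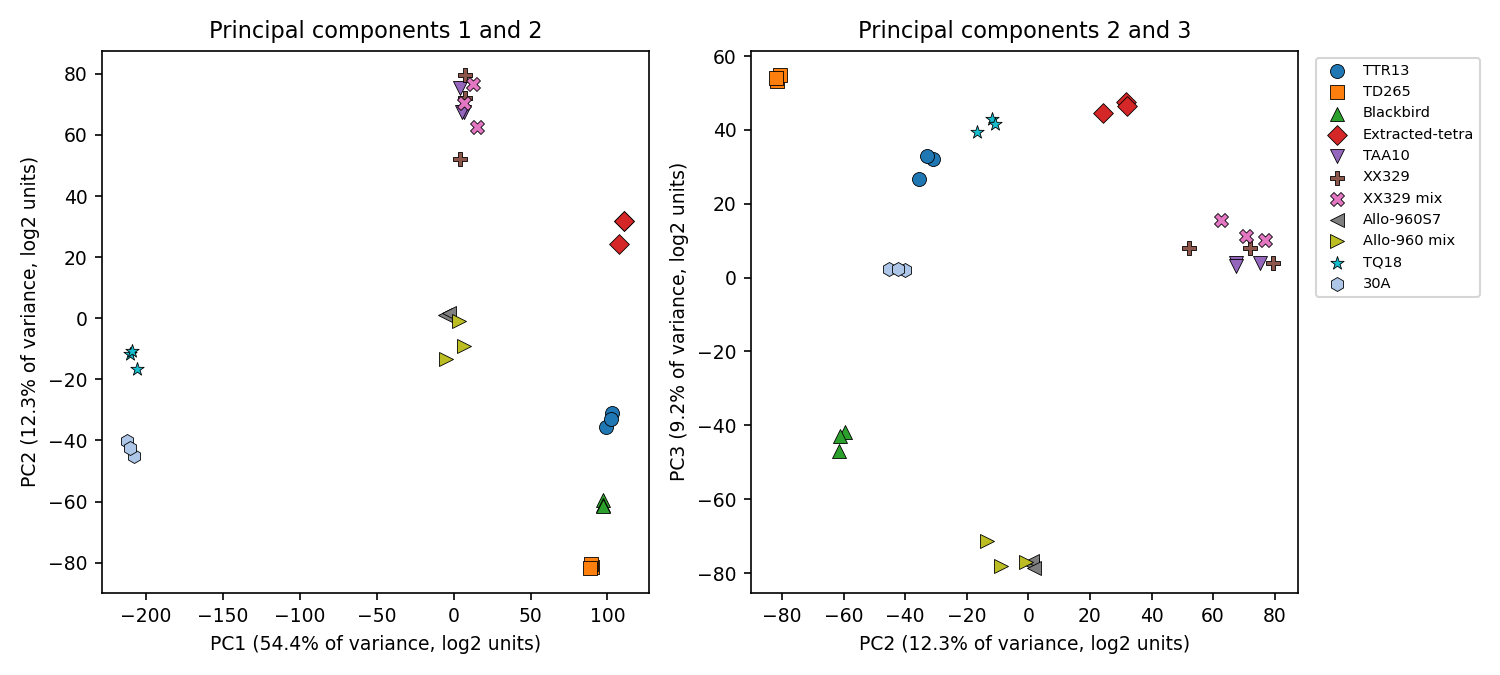
Scores of the 33 arrays on principal components 1 to 3 of the log2 values, 1 point per array, coloured by group; the axes give the share of variance. Component 1 (54.4%) runs from Aegilops tauschii over hexaploids and mixes to the tetraploids.

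Control probe sets divided the arrays into 12 of the Allo-960 family (Blackbird, 30A, Allo-960S7 and Allo-960 mix) and the other 21. The hybridisation controls averaged 9.037 to 9.479 log2 units in the 12 and 9.618 to 10.24 in the 21. Each group lay wholly in 1 of these sets, so in TTR13 or TD265 against Blackbird, TQ18 against 30A and Allo-960S7 against TAA10 this apparent batch and the lines cannot be told apart. The batch can also enter in part wherever Blackbird or 30A is 1 of several lines. This holds for all comparisons with the natural tetraploids, the count apart from each, and the test of TAA10 against TD265 and Blackbird. The actin 3′ minus 5′ difference, taken as a measure of RNA quality, was 0.337 ± 0.245 log2 units in Extracted-tetra and −0.464 ± 0.186 in TAA10 (mean ± SD, n = 3 each). It was −0.406 ± 0.182 in XX329 and −0.139 ± 0.362 in XX329 mix (n = 3 each). The same difference for the ef1a controls had the opposite order, 0.324 ± 0.221 in Extracted-tetra and 0.475 ± 0.175 in TAA10 (n = 3 each). For the gapdh controls it was −2.445 ± 0.437 and −2.597 ± 0.0775 (n = 3 each). So the other control pairs did not show the actin gap, and the actin covariate may not stand for RNA quality.

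Transcripts of the D genome were low in Extracted-tetra and present in every hexaploid and mix. Over 1557 D-enriched probe sets, the median difference from TAA10 was −1.85 in Extracted-tetra, 0.01 in XX329, 0.03 in XX329 mix, −0.13 in Allo-960S7 and −0.02 in Allo-960 mix. The SD of the array medians was 0.031, 0.07, 0.23, 0.033 and 0.12 (n = 3 each). Over 1941 BBAA-enriched probe sets, the median difference from TAA10 was 0.60 (SD 0.043, n = 3) in Extracted-tetra and −0.01 (SD 0.061, n = 3) in XX329. The median difference from a mix calculated at the stated proportions was −0.11 for XX329 mix and −0.12 for Allo-960 mix (SD over probe sets 0.181 and 0.153; r across probe sets 0.9969 and 0.9979).

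**Figure D2:**
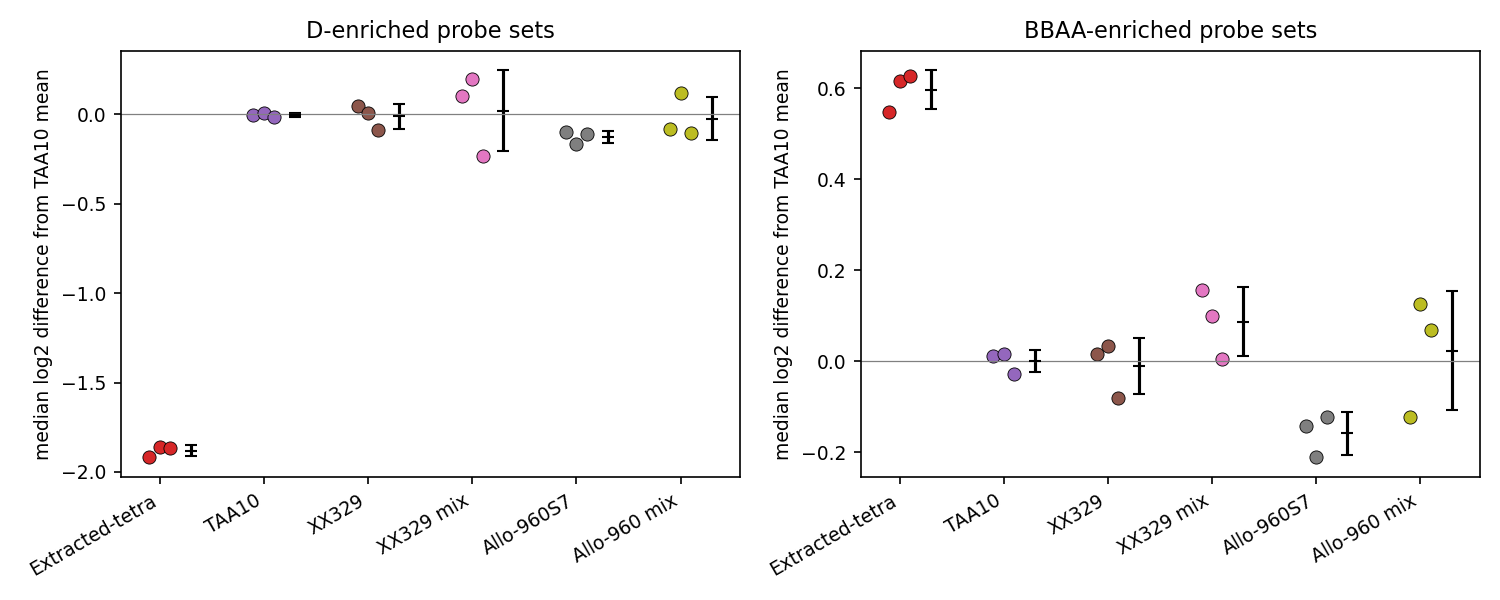
Median log2 difference from the TAA10 mean over D-enriched (left) and BBAA-enriched (right) probe sets, 1 point per array; bars give the mean of the 3 arrays ± SD. Of the 6 groups drawn, Extracted-tetra lies below TAA10, the hexaploids and the mixes on the left and above them on the right.

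Between the Aegilops tauschii lines and the natural tetraploid lines, 51 of the 102 named genes were called. Here n counts arrays, and the p values do not measure the spread between lines. This also holds for Extracted-tetra and TAA10 against the natural tetraploids. The means of the natural tetraploid lines ran from 4.84 to 7.75 for xip and from 5.8 to 7.32 for PIMT, 2 genes given below. LTP3 (LOC543095), a lipid transfer protein, was 4.25 ± 0.25 in Aegilops tauschii (n = 6) and 9.15 ± 0.31 in the natural tetraploids (mean ± SD, n = 9; adjusted p = 4.63e-24). LTP3 and GLU1A (LOC780595), a beta-glucosidase that was lower (4.05 ± 0.48 against 9.57 ± 1.7, n = 6 and 9; adjusted p = 3.5e-10), both lay under the array medians in Aegilops tauschii, so their folds are not secure, and lgul (LOC542984), the glyoxalase that clears methylglyoxal, was 32.9-fold lower (adjusted p = 1.87e-24). The xylanase inhibitor gene xip (LOC542997) was 8.73-fold higher (adjusted p = 2e-16) and PIMT (LOC543193), which repairs damaged aspartyl residues in proteins, 6.1-fold higher (adjusted p = 9.42e-17). The histone gene wcH2B-8 (LOC543184) was 2.85-fold higher (adjusted p = 7.56e-14), although 1 of its 6 other probe sets was called lower and 2 higher. Of the named genes called, 32 were higher and 19 lower. Of the histone list, which holds H2A genes only and not wcH2B-8, 1 of 3 was higher and 2 lower (3 called adjusted over the list alone). Both members of the cold and dehydration list were higher (2 over the list alone), and COR410 was also the sole member of the flowering time list (1 over the list alone). In the pathogenesis-related list, 1 of 4 was higher and 1 lower (2 over the list alone). In each of the antioxidant, carbon fixation, heat shock, root-associated, starch and translation factor lists, 1 member was higher (1 over the list alone). Of the 4 seed storage genes, 1 was higher, with 0 called over the list alone, and the other 5 lists had 0 by either count. In all, 31542 probe sets (51.6%) were called, 18517 higher and 13025 lower, and control centring turned the majority, with 11045 higher and 15673 lower. The count was 28099 within the 21 arrays (TQ18 against TTR13 and TD265) and 23644 within the 12 (30A against Blackbird).

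The natural tetraploids differed widely among themselves. DMAS1 (LOC100037594), an enzyme of phytosiderophore synthesis for iron uptake, was 2.09-fold higher in TTR13 than in TD265 (8.42 ± 0.09 against 7.35 ± 0.08, mean ± SD, n = 3 each; adjusted p = 4.74e-05), with neither of 2 other probe sets called. In the same comparison Prx1 (LOC606328) was 1.85-fold and Glc1 (LOC543469) 1.88-fold higher, with 1 of 3 other Prx1 probe sets called the opposite way. The beta-tubulin gene tubb1 (LOC543257) was 3.05-fold lower, PIMT 2.85-fold lower, and rbcl (LOC100049018), the large subunit of Rubisco, 2.52-fold lower (5 other rbcl probe sets called lower and 1 higher). Against Blackbird, xip was 7.52-fold lower in TTR13 and 5.18-fold lower in TD265. PCS1 (LOC542834), a phytochelatin synthase of metal detoxification, was 1.96-fold and 2.76-fold lower. TTR13 exceeded Blackbird in eIF4E (LOC543485), the cap-binding translation factor, in APRT (LOC543227) and in TBP1, the TATA-binding protein, by 1.38-fold to 1.41-fold, and had 1.68-fold less RPL9 (LOC543077). TD265 exceeded Blackbird in rbcl (3.9-fold), tubb1 (2.21-fold) and PIMT (2.18-fold), and had 1.76-fold less Hmgb3 (LOC543333), a chromatin protein (other probe set not called). Called probe sets numbered 13626 for TTR13 against TD265 (7110 higher), 9942 for TTR13 against Blackbird (5159 higher) and 12305 for TD265 against Blackbird (5870 higher). Control centring lowered the first to 8950, and array weights raised the last. Centring on the hybridisation controls gave 45015 for TTR13 and 47390 for TD265 against Blackbird, 2.21% and 2.95% of them higher in place of 51.9% and 47.7%, and the eIF4E, APRT and TBP1 differences turned negative. With the actin covariate, TTR13 against Blackbird gave 5583 and the calls of eIF4E (0.50 to 0.41 log2 units, SE 0.11 to 0.14), TBP1 (0.47 to 0.51, SE 0.14 to 0.19) and RPL9 (−0.75 to −0.59, SE 0.25 to 0.33) were lost, as was that of tubb1 in TD265 against Blackbird (1.15 to 1.32, SE 0.39 to 0.49). The SE was larger for all 4 calls, and eIF4E and RPL9 were also smaller. For TTR13 against Blackbird, fewer calls in all also made the adjusted cut-off stricter. Leaving out single arrays ended the calls of Glc1, RPL9 and TBP1, and of tubb1 in TD265 against Blackbird. Control centring also ended this tubb1 call (0.54 log2 units, SE 0.41).

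TQ18 and 30A differed in 18 of the 102 named genes. GA20ox1d (LOC543325), a gibberellin synthesis enzyme, was 2.03-fold higher in TQ18 than in 30A (6.94 ± 0.3 against 5.92 ± 0.13, mean ± SD, n = 3 each; adjusted p = 0.000445). The wcH2B-8 histone gene was 2.02-fold and the cation channel gene TPC1 (LOC543074) 1.93-fold higher. PR5 (LOC543292), a thaumatin-like defence protein, was lower (4.42 in TQ18, near the array medians, and 6.58 in 30A), SAHH, of the methyl-donor cycle, 2.27-fold lower, and lgul 1.98-fold lower (the other probe set of SAHH and of lgul not called). In all, 11298 probe sets were called, 5505 higher and 5793 lower. Centring on the hybridisation controls called 53350 (1.08% higher in place of 48.7%) and median centring raised the higher share to 60.6%. A fit limited to these lines gave 5780 and ended the TPC1 and PR5 calls, and the actin covariate gave 5240 and ended the calls of all 3 lower genes. SAHH went from −1.18 to −0.79 log2 units (SE 0.3 to 0.42) and lgul from −0.98 to −0.63 (SE 0.2 to 0.27), both smaller and less precise, and PR5 from −2.16 to −2.40 (SE 0.56 to 0.8), less precise only. PR5 was also lost without replicate 1 of 30A, and the 3 higher genes with control centring.

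Extracted-tetra against TAA10 compares the BBAA genomes alone with all 3 genomes. It does not separate the loss of D transcripts from a change in BBAA expression. DMAS1 was 1.91-fold higher in Extracted-tetra (8.97 ± 0.095 against 8.04 ± 0.042, mean ± SD, n = 3 each; adjusted p = 0.00033), though its 2 other probe sets, at 0.33 and 0.07 log2 units, were not called. TBP1 was 1.84-fold higher (8.86 ± 0.18 against 7.98 ± 0.017, n = 3 each; adjusted p = 3.01e-05). PIMT was 3.19-fold lower (6.45 ± 0.26 against 8.12 ± 0.2, n = 3 each; adjusted p = 3.88e-07). Its mean was 6.44 in the natural tetraploids (n = 9) and 9.05 in Aegilops tauschii (n = 6), so the level in Extracted-tetra was that of tetraploids without a D genome. The other higher genes were the beta-tubulin Tubb5 (LOC543261, 1.81-fold, with 1 other probe set called higher and 2 lower), TPC1 (1.55-fold), LOC543415 (3.49 against 3.11, under the array medians) and eIF4B (LOC543417, 1.29-fold), a translation initiation factor. The other lower genes were PCS1 (1.74-fold), Prx1 (1.64-fold; of 3 other probe sets 1 was called, at −7.06 log2 units, and 2 were not, at −0.30 and 0.14), GAPN (1.41-fold), a glyceraldehyde-3-phosphate dehydrogenase, PEAMT1 (LOC543067, 1.31-fold), which methylates phosphoethanolamine on the way to choline, TCTP (LOC542949, by 0.33 log2 units), the fructose-bisphosphatase FBP (1.23-fold) and AGA.1 (LOC543278, 1.21-fold), the other probe set of FBP and of AGA.1 not being called.

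Of the fixed lists, translation factors had 1 of 3 members higher (1 adjusted over the list alone). Antioxidant enzymes had 1 of 3 lower (2 over the list alone) and carbon fixation 0 of 2 (1 over the list alone), while the other 13 lists had 0 by either count. Across all probe sets, 6900 were higher and 4306 lower in Extracted-tetra, 18.3% of those tested. At 2-fold or more, 881 were higher and 2024 lower. Probe sets lower in Extracted-tetra were mostly ones in which Aegilops tauschii exceeded the natural tetraploids: 3822 (88.8%) were called higher there and 133 (3.09%) lower. Among those higher in Extracted-tetra, 4954 (71.8%) were called lower in Aegilops tauschii and 547 (7.93%) higher. Of all probe sets tested, 30.3% were called higher and 21.3% lower in Aegilops tauschii. With the actin covariate 5513 probe sets were called, 5233 of them shared with the 11206, and DMAS1, TBP1 and PIMT passed while the other 11 named genes did not. Their differences were 72.6% to 123% of those without the covariate (Tubb5 0.85 to 0.64, SE 0.2 to 0.28; PCS1 −0.80 to −0.66, SE 0.21 to 0.29), and the SE, 0.095 to 0.21 before, was 0.14 to 0.3. So most of these calls ended through lost precision, and the stricter adjusted cut-off that fewer calls bring, more than through a smaller fold. Of them, 8 (TPC1, LOC543415, PCS1, Prx1, PEAMT1, TCTP, FBP and AGA.1) were also lost without at least 1 single array. Centring on the hybridisation controls called 7311 and ended 8 of the 14 named calls (TPC1, LOC543415, eIF4B, GAPN, PEAMT1, TCTP, FBP and AGA.1). The differences of these 8 stayed almost as they were (TPC1 0.63 and 0.63, GAPN −0.49 and −0.50), but the SE, 0.095 to 0.19 before, was 0.14 to 0.22. A fit limited to both groups, which leaves the differences as they are, ended the calls of Tubb5 (SE 0.2 to 0.26), Prx1 (SE 0.21 to 0.25), LOC543415, TCTP, FBP and AGA.1.

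**Figure D3:**
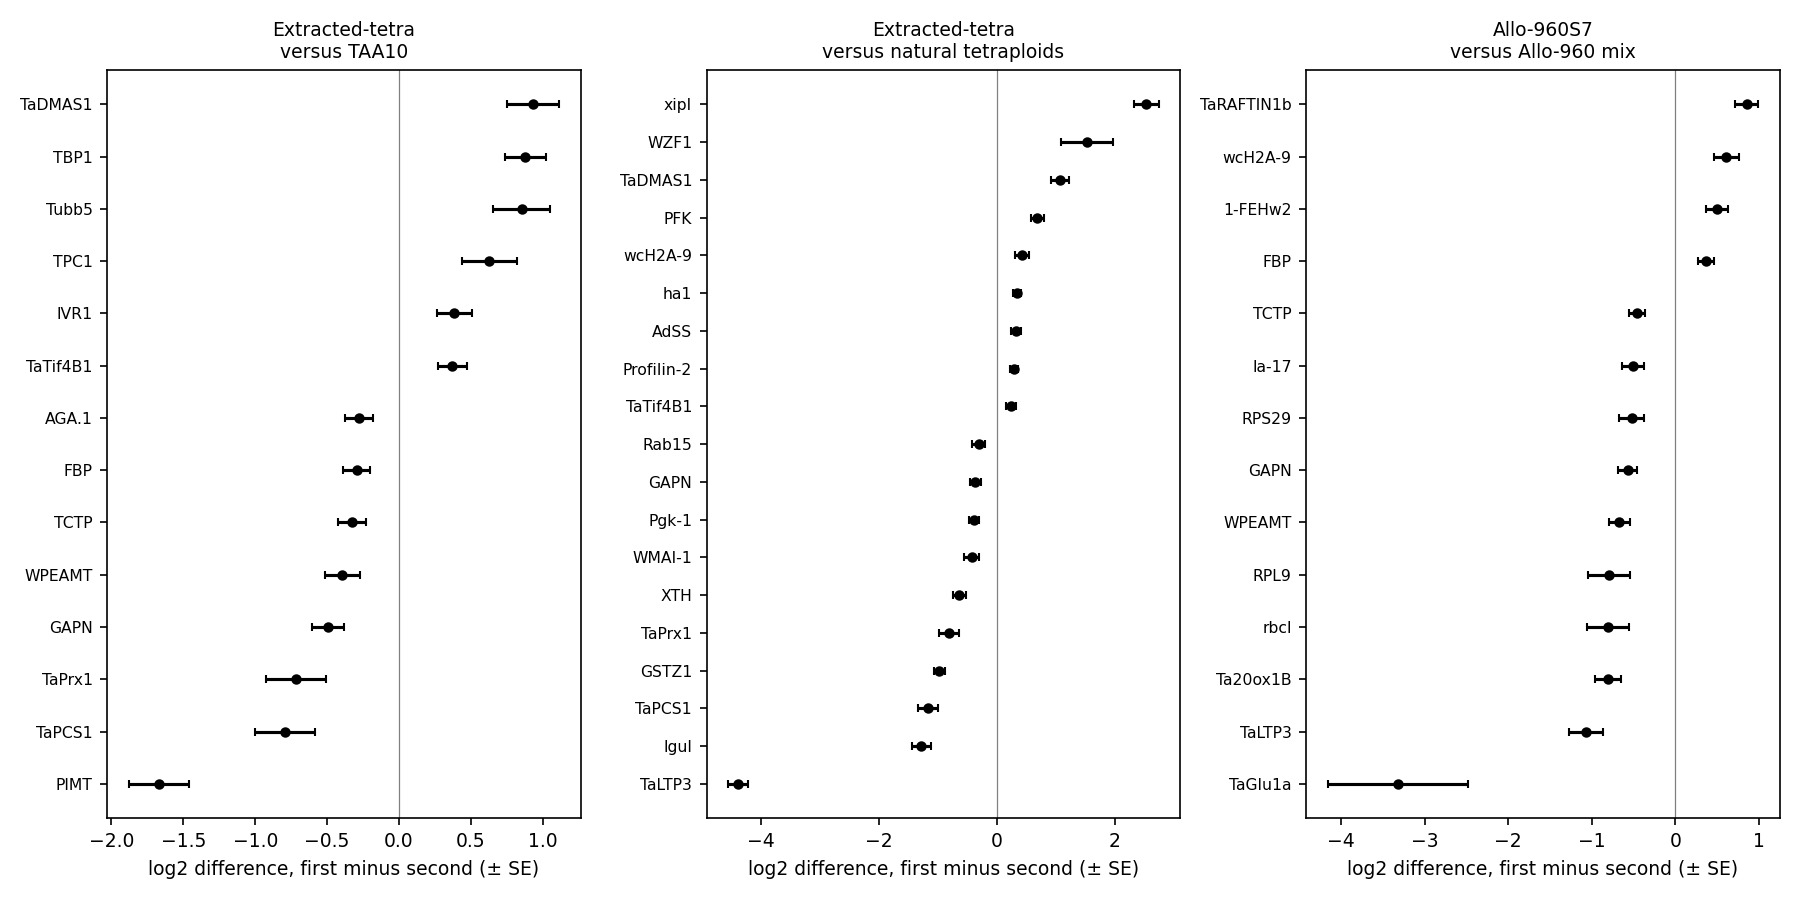
Log2 differences of the named genes called in 3 comparisons (points, first minus second group; bars, ± SE from limma). LTP3 (drawn as TaLTP3) lies far below the other genes in Extracted-tetra against the natural tetraploids, and GLU1A (TaGlu1a) in Allo-960S7 against its mix.

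Extracted-tetra against natural tetraploids compares the BBAA genomes taken out of a bread wheat with those of natural tetraploid lines. It does not separate a change within bread wheat from the loss of the D genome or from a difference between lines. LTP3 was 21-fold lower in Extracted-tetra (4.76 ± 0.26, n = 3) than in the natural tetraploids (9.15 ± 0.31, mean ± SD, n = 9, adjusted p = 8.92e-19), although its other probe set, with a difference of −0.29, was not called. The LTP3 level in Extracted-tetra lay little above the array medians, so the size of this fold is less secure. The xylanase inhibitor xip was higher (8.53 ± 0.049, n = 3, against 5.99 ± 1.4, n = 9; adjusted p = 1.07e-10), and its other probe set was called higher too. Its size depended on the line, with means of 4.84 in TTR13, 5.37 in TD265 and 7.75 in Blackbird (n = 3 each). Blackbird alone of these lay in the set of 12 arrays, so line and apparent batch are not separated here. DMAS1 was 2.11-fold higher (1 of 2 other probe sets called) and PFK, a phosphofructokinase of glycolysis, was higher at levels under the array medians (3.68 ± 0.33, n = 3, against 2.99 ± 0.19, n = 9), where a fold is not secure. Lower genes were lgul (2.42-fold, its other probe set called higher), PCS1 (2.24-fold), GSTZ1 (LOC543412), a glutathione S-transferase (1.96-fold), and Prx1 (1.76-fold, 2 of 3 other probe sets called lower). XTH, which remodels xyloglucan in the cell wall, was 1.55-fold lower. Smaller differences, from 1.18-fold to 1.35-fold, put eIF4B, profilin (LOC543315), AdSS (LOC543243), the proton pump ha1 (LOC543149) and the histone gene H2A-9 (LOC732714) higher. Of the 5 other H2A-9 probe sets only 1 was called, also higher. Rab15 (LOC543293; 3.97 against 4.28, under the array medians), GAPN, Pgk-1 (LOC543496) and the amylase inhibitor WMAI-1 (LOC542981) were lower by up to 1.34-fold. With TD265 left out of the mean the WMAI-1 and Rab15 calls were lost, with Blackbird left out those of eIF4B and AdSS, and with either TTR13 or Blackbird left out that of H2A-9. The zinc finger gene WZF1 (LOC543182) was 2.89-fold higher, but the actin covariate took it from 1.53 (SE 0.44) to 0.08 log2 units (SE 0.62) and ended the call, which was also lost without replicate 3 of Extracted-tetra.

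The antioxidant list had 2 of 3 members lower (2 adjusted over the list alone). In the carbon fixation, cell wall and pathogenesis-related lists 1 member was lower, and in the histone, membrane transporter and translation factor lists 1 was higher (1 over the list alone in each). The other 9 lists had 0 by either count. In all, 14930 probe sets (24.4%) were called, 7806 higher and 7124 lower. In 1764 Extracted-tetra was higher than each natural tetraploid and in 931 lower than each, 2695 in all. The actin covariate gave 4702 and 934 for these counts, and control centring gave 1251 for the second and put 26.1% of the first higher in place of 52.3% and ended the ha1, AdSS, profilin, eIF4B and H2A-9 calls. With the covariate 9 of the 19 genes named here passed, among them LTP3, xip, DMAS1 and GSTZ1. Beside WZF1, the calls of 9 were lost: ha1 (0.35 to 0.30, SE 0.068 to 0.11), AdSS (0.32 to 0.39, SE 0.085 to 0.14), WMAI-1 (−0.43 to −0.58, SE 0.13 to 0.2), Pgk-1 (−0.39 to −0.36, SE 0.083 to 0.14), GAPN (−0.37 to −0.32, SE 0.093 to 0.15), Rab15 (−0.31 to −0.30, SE 0.11 to 0.18), eIF4B (0.23 to 0.17, SE 0.084 to 0.14), H2A-9 (0.43 to 0.29, SE 0.12 to 0.2) and Prx1 (−0.82 to −0.66, SE 0.17 to 0.28). All 9 lost precision, and all but AdSS and WMAI-1 were also smaller. The Rab15, eIF4B, AdSS and H2A-9 calls were lost without single arrays. Taken in the same way among these 4 lines, TD265 differed from the mean of the others in 15534 probe sets and from each of them in 5134, Blackbird in 12359 and 2833, and TTR13 in 9129 and 1445.

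TAA10 had low LTP3, as Extracted-tetra had (4.65 ± 0.13, mean ± SD, n = 3), 22.5-fold under the natural tetraploids (adjusted p = 1.41e-19), with its other probe set also called lower but by only 0.58 log2 units. At 4.65, LTP3 in TAA10 too lay little above the array medians, so the size of the fold is less secure. GSTZ1 was 2.4-fold lower in TAA10 (adjusted p = 6.19e-13, both other probe sets called lower), and GLU1A 16.3-fold lower (adjusted p = 3.2e-05). PIMT was 3.21-fold and PEAMT1 1.33-fold higher, the PEAMT1 call being lost with TD265 left out of the mean, and PFK was higher at levels under the array medians (3.44 against 2.99). The lists for antioxidant enzymes, carbon fixation, the cell wall and pathogenesis-related proteins had 1 lower member each, and membrane transporters 1 higher (1 over the list alone in each). The cold list had 1 of 2 higher (2 over the list alone), flowering time 0 (1 over the list alone), and the other 9 lists 0 by either count. In all, 17985 probe sets were called, 7223 higher and 10762 lower, and control centring put 22.5% of calls higher in place of 40.2% and ended the PFK and PEAMT1 calls.

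Differences of Extracted-tetra from TTR13 were tested in TAA10 against TD265 and Blackbird, a contrast without shared arrays. Of 7457 such probe sets, 67% had the same sign in TAA10, with a median of 0.20 log2 units (fry adjusted p = 4.76e-10). The mean score per array was 0.2 ± 0.0081 in TAA10 (SD, n = 3) and 0.00224 ± 0.034 in the tetraploids (n = 6), and every TAA10 array lay above every tetraploid array (exact permutation p = 0.0119, the smallest that 84 splits allow). These splits exchange single arrays of 3 lines, too few lines to exchange whole, so a trait of TAA10 as 1 line was not told from one of bread wheat. Called in TAA10 in the same direction were 2853, and 1061 in the opposite one.

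XX329 against its RNA mix asks what changes when these BBAA genomes meet a D genome again. Among the 102 named genes only wcH2B-8 differed. It was 1.68-fold lower in XX329 (5.35 ± 0.16 against 6.1 ± 0.41, mean ± SD, n = 3 each; adjusted p = 0.00893), with 1 of 6 other probe sets called lower and 0 higher. The histone list, which does not hold wcH2B-8, had 0 of 3 members called (1 over the list alone), and the other 15 lists had 0 by either count. Across all probe sets 575 were higher and 577 lower, 1.88% of those tested. Against the parents themselves, 80 of the 1152 were above both, 86 below both, 341 between them, 302 apart from Extracted-tetra only, 192 apart from TQ18 only and 151 apart from neither. Replicate 3 of XX329 had the lowest mean r with its own group of any array (0.98265), with replicate 1 next at 0.98398. Its score on principal component 2 was 52.1, against 79.5 and 71.98 in replicates 1 and 2 of XX329. Why it lay apart was not tested. The count was 2260 without replicate 3 of XX329 and 548 without replicate 2 of the mix, which also ended the wcH2B-8 call. It fell to 67 in a fit limited to both groups, which also ended that call, to 666 without the Allo-960 family and to 574 with control centring (22.3% higher in place of 49.9%), which ended the call as well, and rose to 4928 against the calculated mix. For wcH2B-8 the difference was −0.75 (SE 0.16), −0.75 in the limited fit (SE 0.21) and −0.88 with control centring (SE 0.23). So these 2 calls did not end through a smaller difference. The SE was larger, and with fewer calls in all the adjusted cut-off was stricter. Without replicate 2 of the mix the difference was −0.54.

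The 11206 probe sets that set Extracted-tetra apart from TAA10 moved, on balance, a small way toward TAA10 in XX329. The median move from the mix was 0.11 log2 units against a median step of 0.70, and 68.2% of the probe sets had a positive sign (fry adjusted p = 3.01e-05). The score per array was 0.109 ± 0.054 in XX329 and 0.00108 ± 0.027 in the mix (mean ± SD, n = 3 each), with every XX329 array above every mix array (exact permutation p = 0.1, the smallest that 20 splits allow). Called toward TAA10 were 549 and away from it 92. Without replicate 3 of XX329, the array with the lowest r to its own group, the median was 0.072 log2 units. Without replicate 1 it was 0.134. The same measure over the 14930 probe sets that set Extracted-tetra apart from the natural tetraploids, positive further along the direction of Extracted-tetra, had a median of −0.06 (39% positive). This did not pass (fry adjusted p = 0.0723; exact permutation p = 0.5). Without replicate 1 of XX329 its median was −0.10 and the test passed; without replicate 3 the median was near 0.

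XX329 and TAA10 were close, with r across probe sets of 0.9904 between group means. The beta-tubulin tubb2 (LOC543258) was 1.95-fold higher in XX329 (11.4 ± 0.11 against 10.5 ± 0.25, mean ± SD, n = 3 each; adjusted p = 0.00802). Raftin1b (LOC543009), known from anthers, was 1.51-fold higher, and GSTZ1 1.39-fold higher, with no other probe set of either called. The antioxidant list had 1 of 3 higher (1 over the list alone), carbon fixation 0 (1 over the list alone) and the other 14 lists 0 by either count. In all, 1311 probe sets were called, 499 higher and 812 lower. The count was 2419 without replicate 3 of XX329, 539 in a fit limited to both groups and 2572 with control centring (6.69% higher in place of 38.1%). Replicate 3 of XX329 was the array with the lowest r to its own group. The tubb2 call was lost without replicate 1 or 2 of TAA10, that of raftin1b without replicate 1 of TAA10 or of XX329, and that of GSTZ1 without replicate 2 of XX329; control centring ended all 3, and the limited fit those of raftin1b and GSTZ1.

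XX329 mix differed from TAA10 in 2310 probe sets, 1032 higher and 1278 lower. GA20ox1d was 1.99-fold higher in the mix (5.85 ± 0.21 against 4.85 ± 0.15, mean ± SD, n = 3 each; adjusted p = 0.00211), rbcl 1.9-fold (0 of 27 other probe sets called higher and 1 lower) and wcH2B-8 1.8-fold. AGP-S (LOC543299), the small subunit of the first committed enzyme of starch synthesis, was 1.29-fold lower. The antioxidant and carbon fixation lists had 1 higher member and starch metabolism 1 lower (1 over the list alone in each), translation factors 0 (1 over the list alone), and the other 12 lists 0 by either count. Array weights gave 3728, and control centring put 21.8% of calls higher in place of 44.7% and ended the rbcl, wcH2B-8 and AGP-S calls, the last 2 of which a fit limited to both groups ended too. The rbcl call was lost on leaving out any array but replicate 2 of TAA10, and that of AGP-S on leaving out any but replicate 1 of the mix and, through a larger SE, with the actin covariate (−0.37 to −0.36, SE 0.097 to 0.11).

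Allo-960S7 against its RNA mix asks the same of a hexaploid from a natural tetraploid. Raftin1b was 1.8-fold higher (5.8 ± 0.085 against 4.95 ± 0.11, mean ± SD, n = 3 each; adjusted p = 0.000106), its other probe set not being called. H2A-9 was higher (4.83 against 4.22, the mix under the array medians), but 0 of its 5 other probe sets were called, and against the calculated mix it was 0.26 log2 units and not called. The fructan hydrolase 1-FEH (LOC543441) was 1.41-fold and FBP 1.28-fold higher (other FBP probe set not called). LTP3 was 2.09-fold lower (7.31 ± 0.29 against 8.38 ± 0.21, n = 3 each; adjusted p = 0.000592, its other probe set called lower too). PEAMT1 was 1.59-fold, GAPN 1.49-fold, la-17 (LOC543289) 1.42-fold and TCTP 1.37-fold lower. GA20ox1b (LOC543326), a gibberellin synthesis enzyme, was 1.75-fold lower. Both ribosomal protein genes of the list were lower, RPL9 by 1.74-fold and RPS29 (LOC606342) at 4.19 against 4.71, under the array medians in Allo-960S7 (2 over the list alone), the other RPS29 probe set not being called. The rbcl probe set read 1.75-fold lower, but 4 of its 27 other probe sets were called higher and 0 lower. GLU1A was 10-fold lower with a wide spread in the mix (10.2 ± 2.7, n = 3), and its call was lost without replicate 2 or replicate 3 of the mix and, like that of FBP, in a fit limited to both groups. The RPL9 call was lost on leaving out any 1 of the arrays, and the rbcl call on leaving out any but replicate 2 of Allo-960S7. Without that replicate the 1-FEH, FBP, RPS29 and la-17 calls were lost. Those of 1-FEH and la-17 were also lost without replicate 1 of Allo-960S7 or replicate 2 of the mix. That of FBP was also lost without replicate 1 of the mix, and that of RPS29 without replicate 3 of Allo-960S7 or replicate 2 or 3 of the mix.

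The histone list had 1 of 3 higher (1 over the list alone) and starch metabolism 1 of 4 higher (2 over the list alone). Carbon fixation and pathogenesis-related proteins had 1 lower (1 over the list alone in each). Antioxidant and secondary metabolism lists had 0 (1 over the list alone in each), translation factors 0 (2 over the list alone) and the other 8 lists 0 by either count. In all, 5227 probe sets were called, 2017 higher and 3210 lower, 8.54% of those tested. Against the parents, 683 were above both and 953 below both, 1081 lay between them, 1288 were apart from Blackbird only, 897 apart from 30A only and 325 apart from neither. The count was 3364 without replicate 2 of Allo-960S7 and 3349 without replicate 2 of the mix. It was 2847 with control centring, which ended 8 of the 14 calls named (1-FEH, FBP, rbcl, RPL9, GAPN, RPS29, la-17 and TCTP), 12553 with array weights and 8487 against the calculated mix.

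Probe sets that departed from the mix in both hexaploids were more than expected for independent calls. The expected counts take every probe set as equally likely to be called. Both contrasts also share 1 variance estimate per probe set, so some excess can arise without a shared departure. Higher in both were 83 (19 expected) and lower in both 169 (30.3 expected), while 34 (30.2 expected) were higher in XX329 and lower in Allo-960S7 and 53 (19 expected) the reverse. The departures correlated with r = 0.131 across probe sets, which are not independent replicates. The 12849 probe sets that set Extracted-tetra apart from TTR13 and TD265 did not move together in Allo-960S7 against its mix (median −0.03, 45.2% positive; fry adjusted p = 0.675; exact permutation p = 0.4).

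Allo-960S7 against TAA10 compares the synthetic hexaploid with bread wheat. LTP3 was 6.31-fold higher in Allo-960S7 (7.31 ± 0.29 against 4.65 ± 0.13, mean ± SD, n = 3 each, adjusted p = 1.97e-11), but its other probe set was called lower, by 0.73 log2 units. The LTP3 level in TAA10 lay little above the array medians. PR5 was higher (5.85 against 3.91, TAA10 being under the array medians), a call lost without replicate 3 of Allo-960S7, and lgul 2.14-fold higher, its other probe set called lower. COMT1 (LOC543449), of lignin synthesis, was 1.69-fold lower, PEAMT1 1.66-fold and AdSS, of purine synthesis, 1.52-fold. The antioxidant list had 2 of 3 higher and pathogenesis-related proteins 2 of 4 (2 over the list alone in each). Carbon fixation had 1 of 2 and starch metabolism 1 of 4 higher (2 over the list alone in each), and cell wall and translation factors 1 higher (1 over the list alone in each). Cold and secondary metabolism lists had 1 lower (1 over the list alone in each), ribosomal proteins 0 (2 over the list alone), and the other 7 lists 0 by either count. In all, 13440 probe sets were called, 6385 higher and 7055 lower. Control centring gave 36887 (94.8% higher in place of 47.5%) and ended the calls of the 3 lower genes. The actin covariate gave 8131 and ended the calls of lgul (2.14-fold before, 0.77 log2 units with it, SE 0.2 to 0.27), smaller and less precise, and PR5 (1.93 to 2.16, SE 0.56 to 0.78), less precise only. The COMT1 call was lost without replicate 1 or 2 of either group.

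**Figure D4:**
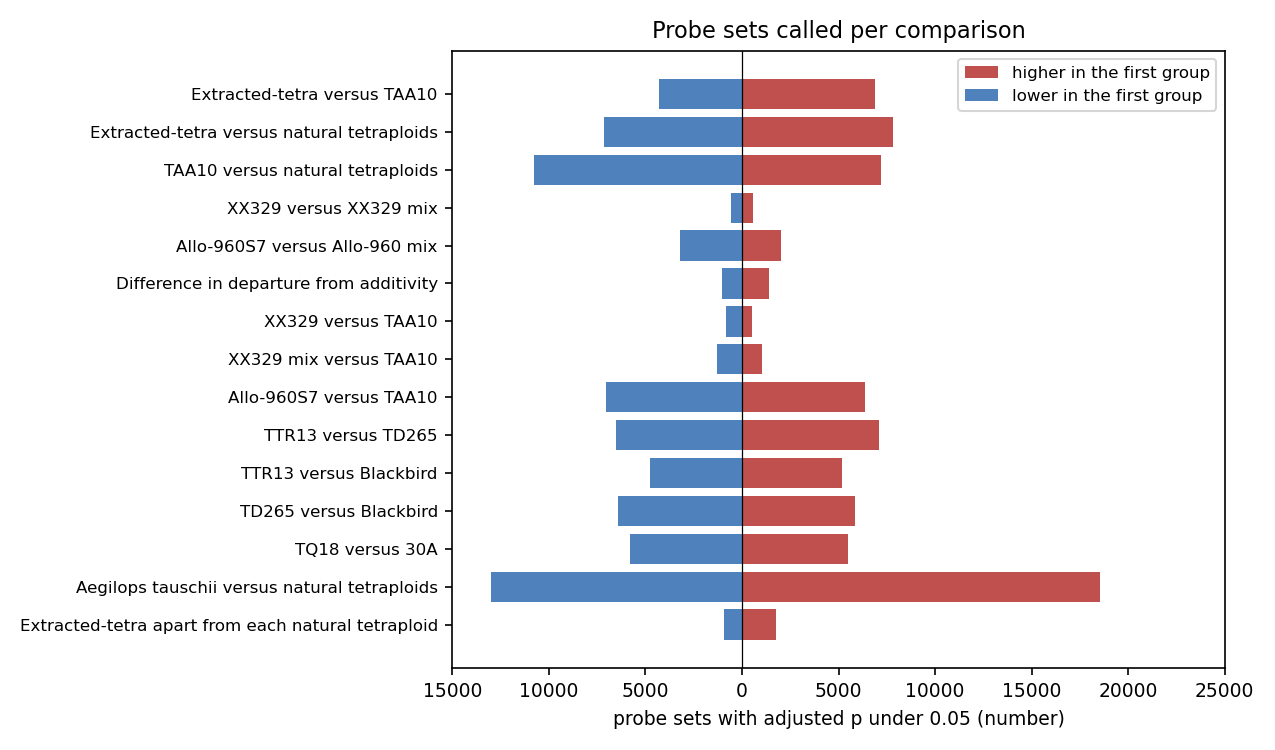
Number of probe sets called per comparison with limma at an adjusted p under 0.05; bars to the right are higher and bars to the left lower in the group named first. XX329 against its mix (1152) and against TAA10 (1311) have the shortest bars and Aegilops tauschii against the natural tetraploids (31542) the longest.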

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

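The tests of equal RNA input and of array scaling, the exchange of whole lines, the mixing test over D-enriched probe sets, the covariate for RNA quality as a setting and every count of other splits of the arrays were chosen only after the results were seen.

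The departures of the hexaploids from their mixes differed from each other in 2461 probe sets by the interaction contrast (limma), 1421 more positive in XX329 and 1040 more positive in Allo-960S7; 87 were called in both hexaploids with opposite signs. Control centring turned the majority and lowered the count to 1190, with 357 more positive in XX329 and 833 in Allo-960S7. A fit limited to these groups lowered the count too, while array weights raised it. Among named genes the difference, XX329 minus Allo-960S7, was 0.626 log2 units for GAPN (SE 0.16, adjusted p = 0.0214), 0.468 for TCTP (SE 0.13, adjusted p = 0.0438) and 1.19 for tubb2 (SE 0.3, adjusted p = 0.0191). It was 0.52 for AGA.1 (SE 0.14, adjusted p = 0.0253), 1.03 for GA20ox1b (SE 0.23, adjusted p = 0.00606) and 0.698 for the thionin gene THI1.1 (SE 0.18, adjusted p = 0.0224), whose 4 group means, 3.16 to 3.65, all lay under the array medians of 4.37 to 4.481, so that its size is not secure. GAPN, TCTP and GA20ox1b were lower than the mix in Allo-960S7 (−0.571, −0.457 and −0.807) and differed by 0.0543, 0.0112 and 0.223 in XX329, which did not pass. The departures of tubb2 (0.602 in XX329 and −0.586 in Allo-960S7), AGA.1 (0.298 and −0.221) and THI1.1 (0.325 and −0.374) passed in neither hexaploid. Of 100 splits of these arrays 6 gave as many calls, up to 4361, so chance was not excluded for the count. The ribosomal, pathogenesis-related, starch and translation factor lists had 0 members called and 1 each adjusted over the list alone, and the other 12 lists 0 by either count.

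XX329 moved from its RNA mix toward TAA10 by a median of 0.11 log2 units over 11206 probe sets. A mix with less diploid RNA than stated would leave probe sets with like parents in place, but over 1032 with parents within 0.25 log2 units the median was 0.0742, with array scores of 0.0752 ± 0.039 in XX329 and −0.000793 ± 0.036 in the mix (mean ± SD, n = 3 each). Chance error of Extracted-tetra carried into the mix by shared RNA would fade where the step is large, but the 110 of these with a 2-fold step moved by 0.0912, although that was 5.13% of the step against 15.9% over all. With the actin covariate the median over all 11206 was 0.0968. This argues against RNA quality as the whole cause only as far as actin reads it. For the near-equal parents regulation in the hexaploid nucleus predicted a median above 0, which 0.0742 met, but no size. These probe sets are part of the 11206, and causes other than the mixing ratio could give the same sign. Such regulation may account for this part, as a hypothesis only. For the whole set a different mixing ratio stays open, because over D-enriched probe sets XX329 minus the mix was −0.0227, within the spread of the mix arrays.

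The control probe sets set the 12 arrays of the Allo-960 family apart from the other 21, as an array batch or handling could. Differences across the sets that share no array (TQ18 minus 30A; TTR13 and TD265 minus Blackbird) correlated across probe sets with r = 0.122 and Spearman rho = 0.221, and 1065 probe sets were called the same way against 279 the opposite way. A pair within the 21 arrays (TTR13 minus TD265) gave r = 0.0883 with TQ18 minus 30A, so these values decide neither for a batch nor for line differences alone. Batch and line cannot be told apart here because each group lies in 1 set. Each hexaploid and its own mix lay in the same set. Extracted-tetra against the mean of TTR13 and TD265, without Blackbird, lay within the 21 arrays and called 12849 probe sets.

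BBAA-enriched probe sets were higher in Extracted-tetra than in TAA10 by a median of 0.596 log2 units. A scaling of whole arrays would raise the hybridisation controls alike, but these differed by 0.0037 (pooled SD of the arrays 0.108, n = 3 each), which argues against array scaling. Equal RNA input without a D genome would raise BBAA transcripts by up to 0.585, the log2 of 3 over 2, and stays open. The median against the XX329 mix was 0.514, but that mix is diluted Extracted-tetra RNA, so its step is fixed by its making and decides nothing. Altered regulation of the BBAA genes was not tested and stays open too.

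For the other counts, the splits of 3 arrays against 3 were too few, at 10, for a share under 0.05. The real count, with the highest of the other splits after it, was 11206 and 4 for Extracted-tetra against TAA10, 1152 and 699 for XX329 against its mix, 5227 and 2 for Allo-960S7 against its mix, and 2310 and 0 for XX329 mix against TAA10. It was 13440 and 12 for Allo-960S7 against TAA10, 13626 and 1 for TTR13 against TD265, 9942 and 21 for TTR13 against Blackbird, and 12305 and 1 for TD265 against Blackbird. For TQ18 against 30A it was 11298 and 86, and the other splits that part all 3 numbered pairs called 25 to 30 while those that part 1 pair called 24 to 86. For XX329 against TAA10 it was 1311, and 2 of the 10 splits, the real one included, gave as many, with 1726 in the other. Of 100 splits of larger groups only the real one reached 14930 for Extracted-tetra (highest other 11284) and 17985 for TAA10 (11496) against the natural tetraploids, and 31542 for Aegilops tauschii (19497). For Extracted-tetra apart from each natural tetraploid 2 of 100 reached 2695 (highest other 4980). For these 4 counts few splits of single arrays reached the real count. The other splits mix arrays of unlike lines and gave a median of 0 calls. A small share therefore shows little beyond a difference between lines, and such splits do not exchange whole lines. With lines exchanged, TD265 against the other 3 lines of the Extracted-tetra comparison gave 15534 calls, more than the 14930 of Extracted-tetra, and stood apart from each in 5134, as Blackbird did in 2833. So these counts do not set Extracted-tetra apart from natural lines. Against the other lines of the TAA10 comparison TD265 gave 16335, under the 17985 of TAA10, but 4 lines are too few for a share under 0.05, and lines were not exchanged for Aegilops tauschii.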

How the results depend on the processing

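The covariate, the fit without 12 arrays, the sets within 21 or 12 arrays, Blackbird left out of the count apart from each tetraploid, and the added gene groups were chosen after seeing the data; the other alternatives were planned. The move toward TAA10 in XX329 and the TAA10 differences shared with Extracted-tetra kept direction and call under every alternative run with a test, with medians of 0.0716 to 0.134 and 0.191 to 0.230 on leaving out each array, while both directed sets that had not passed changed sign under some. The planned gene list test was not run because no list reached 5 genes. The cause of the values below was not tested, with 2 exceptions. A 2-fold minimum calls less by construction. Control centring subtracts each array's control mean from every probe set, so its median shifts follow by construction from the control means. These were 9.781 in TTR13 and 9.209 in Blackbird, and the shift for that pair was −0.573. Why the control means differ was not tested. Fits with fewer arrays went both ways, with 548 to 2260 for XX329 against its mix on leaving out each array. Differences under about 1.5-fold lie where the simulated data recovered 58% or less, and the smallest change simulated was recovered in 0% to 6%. The simulated data held fewer changed probe sets than were called in the comparisons they stood for. Their adjusted cut-off was therefore stricter, and these shares may understate the recovery in the real data. Errors shared across an array were not simulated, and their effect on these shares is not known.

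With a 2-fold minimum the counts were 2905 (Extracted-tetra against TAA10), 2310 (Extracted-tetra against natural tetraploids), 658 (apart from each), 3740 (TAA10 against natural tetraploids), 284 (XX329 against mix), 1415 (Allo-960S7 against mix), 1244 (interaction), 570 (XX329 against TAA10), 733 (XX329 mix against TAA10) and 3149 (Allo-960S7 against TAA10). They were 3568, 2327 and 3848 for TTR13 against TD265, TTR13 against Blackbird and TD265 against Blackbird, 1954 for TQ18 against 30A and 10758 for Aegilops tauschii. The move along the Extracted-tetra difference from natural tetraploids was −0.122 and passed, and that in Allo-960S7 was 0.0413. The label check with 2-fold in place of 4-fold gave −0.987.

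Centring on the hybridisation controls gave 7311 for Extracted-tetra against TAA10, 574 for XX329 and 2847 for Allo-960S7 against the mix, 1190 for the interaction (30% positive in place of 57.7%), 2572 and 36887 for XX329 and Allo-960S7 against TAA10, 8950, 45015 and 47390 for the tetraploid pairs in the order above, 53350 for TQ18 against 30A and 1251 apart from each. It put 41.3% of the Aegilops tauschii calls higher in place of 58.7%. It shifted the median of all probe sets by −0.75 (TQ18 against 30A), −0.60 (TD265) and −0.57 (TTR13 against Blackbird), 0.46 (Allo-960S7) and −0.27 (XX329 against TAA10). Shifts were −0.14 for Extracted-tetra, TAA10 and Aegilops tauschii against natural tetraploids and XX329 mix against TAA10, −0.13 for XX329 against its mix and −0.145 for the interaction. The move along the natural tetraploid difference became 0.0340 and the label check −2.24; eIF4E, APRT and TBP1 in TTR13 against Blackbird became −0.0765, −0.0895 and −0.104. Quantile normalization again gave −0.0544 (passed) for that move and −1.80 for the label check.

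Array weights gave 12553 (Allo-960S7 against mix), 4181 (interaction), 3728 (XX329 mix against TAA10) and 18558 (TD265 against Blackbird). Fits limited to the groups compared gave 67 (XX329 against mix), 1262 (interaction), 539 (XX329 against TAA10) and 5780 (TQ18 against 30A). Against calculated mixes XX329 had 4928 and Allo-960S7 8487 calls, the move toward TAA10 was 0.163 and that in Allo-960S7 0.0166. Without the 12 arrays XX329 against its mix had 666. The actin covariate gave 5513 and 4702 for Extracted-tetra against TAA10 and natural tetraploids, 934 apart from each, 8131 for Allo-960S7 against TAA10, 5583 for TTR13 against Blackbird, 5240 for TQ18 against 30A and −0.125 (passed) for the move along the natural tetraploid difference; the move toward TAA10, over probe sets selected anew, was 0.160. Geometric weights put the mixes at −0.0762 and −0.0868 from the calculated ones, and without the dimmest 33.3% of probe sets XX329 mix was at −0.121. With the replicate block every count stayed within 1.5 times its value (11075 for Extracted-tetra against TAA10).

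Leaving out each array gave 548 to 2260 for XX329 against its mix, 974 to 2419 for XX329 against TAA10, 3349 to 5060 for Allo-960S7 against its mix and −0.100 to 2.66e-05 for the move along the natural tetraploid difference, where the test passed without replicate 2 or 3 of Extracted-tetra, replicate 1 or 2 of XX329, or replicate 3 of XX329 mix. The other counts stayed within 1.5 times their value. The counts of 2260 and 2419 came without replicate 3 of XX329, the array with the lowest r to its own group.

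Of the added gene groups, 0 of 84 camera tests were called with the preset or an estimated correlation (lowest adjusted p 0.926), and fry called 21. Among named genes under alternatives and other probe sets, 1734 values kept direction and call, 303 lost the call, 53 moved and 16 reversed. Reversed other probe sets read −1.62 and −1.25 for Tubb5, 1.83 for lgul (Extracted-tetra against natural tetraploids) and −4.34 (Allo-960S7 against TAA10). For rbcl they read 0.551, 0.688, 0.787 and 0.754 (Allo-960S7 against mix), −1.06 (XX329 mix) and 0.619 (TTR13 against TD265). They read −0.729 for LTP3 (Allo-960S7 against TAA10), −0.464 for Prx1 (TTR13 against TD265) and −0.619 for wcH2B-8 (Aegilops tauschii).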
